A study of Rattus norvegicus with 4 samples.

How the data were processed

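Gene expression was measured on 4 one-colour Affymetrix rat arrays, 2 of wild-type and 2 of homozygous Pax6 mutant (rSey2/rSey2) telencephalon at E11.5, embryonic days counted from the vaginal plug. The telencephalon is the front part of the embryonic forebrain, and Pax6 is a transcription factor of the paired-box family. Per the labels, the background was Sprague-Dawley, the dissected tissue went into TRIZOL, and biotin-labelled cRNA was made from 10 µg of total RNA. The design text names 13 telencephalons and a repeat in each genotype, so each array stands for pooled embryos. It does not settle whether each array had its own pool of 13. The labels call the arrays of a genotype biological replicates. They do not name the litters, so the p-values measure the spread between these arrays, part of which may be technical.

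The deposited table holds 1 value per probe set and array on the log2 scale, made by the authors with GCRMA, per the submitters' processing notes; the software version was not given in the sources used here. GCRMA subtracts a background predicted from probe sequence, normalizes between arrays and summarises the probes of a probe set. The log2 scale was read from the values, which ran from a shared lowest value of 2.07 to 16.13. Between 5333 and 5462 probe sets per array lay exactly at that lowest value, where no difference can be measured. The median over tested probe sets was 8.24 and 8.33 in the wild-type arrays and 8.22 and 8.35 in the mutant arrays. Arrays give no read depth, and the number of arrays limits the precision.

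Of 31099 probe sets, 57 controls were left out. Of the remaining 31042, the platform annotation gave 1 gene symbol to 20826, several symbols to 436 and none to 9780, which are unnamed here. Entrez identifiers of 20764 probe sets matched the RefSeq gene table, and 0 symbols changed through that match. Genes were named only from probe sets with 1 symbol, 14217 genes in all. No genomic position is given, since the sources used here name no genome build for the array table. The order of genes along the chromosomes in the RefSeq table was used for a single check in the closing section.

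Probe sets whose mean over the 4 arrays lay under the 40th percentile, at 3.21 on the log2 scale, were left out as dim (12417 probe sets), and 18625 were tested. The deposited values were not normalized again. limma (version 3.58.1, in R 4.3.3) fitted genotype as the single term with lmFit and eBayes, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Differences are mutant minus wild type on the log2 scale, with the moderated standard error (SE) and n = 2 arrays per genotype. The replicate number was not a term of this model. An exact permutation test of 2 arrays against 2 has 3 splits and cannot give a two-sided p under 0.333, so none is reported. Probe sets that differed by at least 1 on the log2 scale in all 4 pairings of a mutant with a wild-type array were counted without a test.

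Gene lists (27) were written from textbook knowledge of the tissue, with lists for neighbouring tissues and blood. Each gene was represented by its probe set with the highest mean, which left 9840 genes, and lists with at least 5 tested genes were tested with limma's camera with a preset correlation of 0.01. The 23 tested lists shared 1 Benjamini-Hochberg adjustment. camera with an estimated correlation and fry were run beside it. For members of a list, p-values were also adjusted over the list alone. This makes no correction across lists and depends on list size, so passing there is weaker than passing over all probe sets. The list of published Pax6 targets may include genes first picked on these or similar samples, so its direction is not independent evidence.

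The genes named were Pax6, then up to 12 increases and 12 decreases with the largest change past the threshold. Free places went to genes with an unadjusted p under 0.01, a log2 change of at least 1 and no overlap between the groups. Members passing over their list alone, and up to 3 members with the largest change in each developmental list, were added. The groups, tests, filter, gene lists, naming rule and most alternatives were fixed before the data were examined.

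The procedure was tested on simulated data that had the spread of each probe set and 18625 tested probe sets. It recovered 70% of 40 decreases of 4 on the log2 scale, 35% of decreases of 2 and 2.5% of decreases of 1, with 0 false calls. It recovered 35% of increases of 2 and 12.5% of increases of 1. With the same SD given to all probe sets it recovered 100% at each of these sizes, with 7 false calls. The simulated noise was independent between arrays, with no difference shared by same-numbered arrays. In the first setting the SD seen in the 4 arrays was taken as the true SD. These rates may therefore not hold for the data. camera called a simulated list of 20 genes shifted by 0.5 and 0 of 20 random lists. These simulated genes varied independently with the same SD. The check therefore does not cover lists whose genes vary together, as several lists did in the data.

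The alternatives were no filter and a stricter filter on dim probe sets (60th percentile), quantile normalization, median centring of the arrays, a trend or robust prior in eBayes, the replicate number as a block, an unmoderated test, a pseudocount of 16 and a looser threshold of 0.1. Others were the mean of all probe sets of a gene in the list tests and leaving out each array in turn. Leaving out an array leaves 1 array in a group, which is then assumed to vary like the other group. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.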

Results

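The comparison asked which transcripts differ between wild-type and homozygous Pax6 mutant rat telencephalon at E11.5, with 2 arrays of pooled tissue per genotype. Fabp7, which encodes a fatty-acid-binding protein of neural progenitors, differed most: its GCRMA value was 11.99 ± 0.23 (SD, n = 2) in wild type and 4.73 ± 0.23 (SD, n = 2) in the mutant. This difference of -7.26 (SE 0.19) corresponds to a 153.5-fold lower level. With a pseudocount of 16 the difference was -6.58, so the exact fold depends on how low values are treated. Dmrta1, a DM-domain transcription factor of the dorsal telencephalon, was at 8.70 ± 0.13 in wild type and 5.73 ± 0.80 in the mutant, a difference of -2.97 (SE 0.45). Dkk3, a Dickkopf family member, differed by -1.56 (SE 0.11); its other probe sets were dim.

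Pax6 itself (1 tested probe set) had a value of 11.80 ± 0.07 (SD, n = 2) in wild type and 11.71 ± 0.11 (SD, n = 2) in the mutant. The difference of -0.09 (SE 0.10) was within the spread between arrays (limma, adjusted p = 1), with a 95% interval from -0.39 to 0.20. The sources used here do not give where the rSey2 lesion lies relative to this probe set, so the Pax6 transcript level does not check the genotype labels.

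Over all 18625 tested probe sets, 0 passed an adjusted p of 0.05 in limma. The unadjusted p was under 0.05 for 680 probe sets, where 931 would be expected by chance. The lowest adjusted p was 0.196, shared by Fabp7 (unadjusted p = 2.11e-05) and Prr15 (unadjusted p = 1.57e-05). Fabp7 passed with the stricter filter (adjusted p = 0.00784). Both genes passed after quantile normalization (adjusted p = 0.0148) and after median centring, where Fabp7 had an adjusted p of 0.00317 and Prr15 of 0.0057. Both also passed without the probe sets of zero variance, a choice made after seeing the data (adjusted p = 0.0395). Over all alternatives the adjusted p of Fabp7 ran from 0.00317 to 1.

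The naming rule gave 12 genes with lower and 5 with higher values in the mutant, all of which missed the threshold over all probe sets. Below Fabp7 in size came Prr15, from 6.80 ± 0.08 to 2.20 ± 0.14 (SD, n = 2), a mutant value under the dim level of 3.21. Map7, a microtubule-associated protein, differed by -3.47 (SE 0.30). A second Map7 probe set differed by -2.78, with a mutant value of 2.33 under the dim level, and another, dimmer one differed by -0.23. The other lower genes were Ralyl (-2.10), Sapcd1 (-2.02), the calcium-binding protein calbindin Calb1 (-1.85), Rcsd1 (-1.79), Ramac (-1.78), Emilin2 (-1.68), Fez1 (-1.66) and the arginase Arg1 (-1.58). Fez1, which takes part in axon growth, had little spread: 11.15 ± 0.01 in wild type and 9.49 ± 0.01 in the mutant (SD, n = 2; limma adjusted p = 0.523). The mutant value of Ralyl was also under the dim level. With a pseudocount of 16, Prr15 differed by -2.63, Ralyl by -0.97 and Rcsd1 by -1.02.

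The 5 genes with higher values were Kcnip4 (1.73), which encodes a potassium channel-interacting protein, the transcription factor Npas3 (1.12), Slitrk1 (1.07), the ephrin Efna1 (1.05) and the axon guidance receptor Robo3 (1.04). Wild-type values of Kcnip4 and Robo3 were under the dim level. A brighter Efna1 probe set differed by 0.12 (SE 0.10; 0.06 without wild-type replicate 1 or mutant replicate 1, 0.19 without wild-type replicate 2), so the probe sets of Efna1 disagree. With the pseudocount all 5 lay under the log2 limit of 1, with Kcnip4 at 0.88, Npas3 at 0.62, Slitrk1 at 0.74, Efna1 at 0.58 and Robo3 at 0.44. In all, 9 higher and 33 lower probe sets met the same limits, of which 4 higher and 6 lower had no single symbol. The naming rule stops at 12 genes, so further lower genes such as Dkk3 and Rassf4 met them too.

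**Figure D1:**
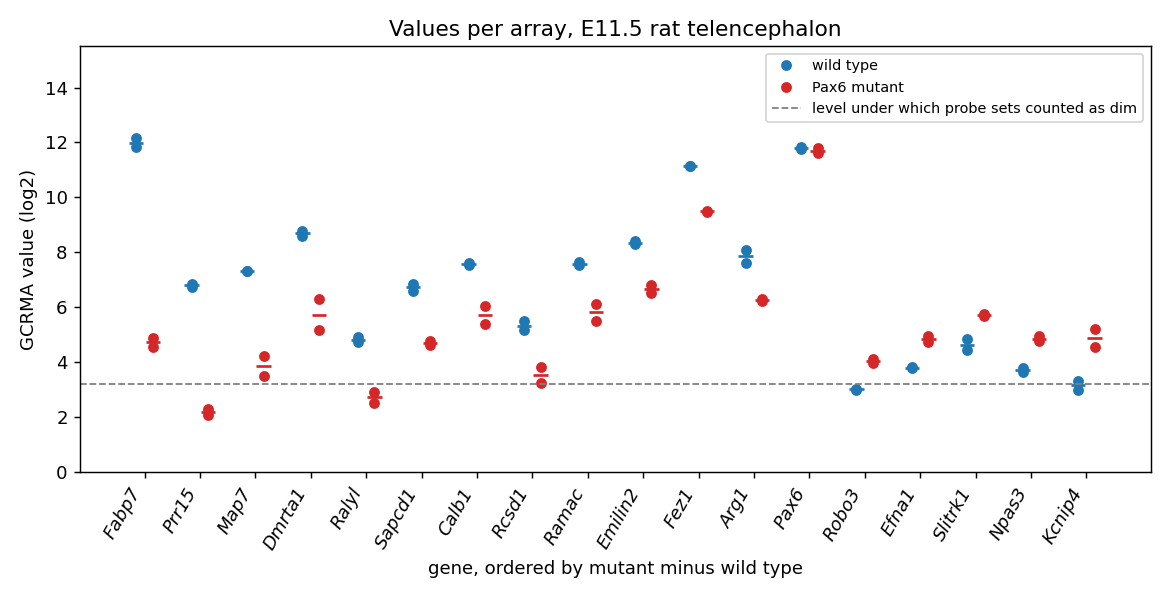
GCRMA values (log2, vertical axis) of each array for Pax6 and the genes with the largest differences, ordered by mutant minus wild type; points are arrays, short bars are means of n = 2, and the dashed line is the dim level of 3.21. Fabp7 lies at 11.99 in wild type and 4.73 in the mutant on average, while the Pax6 values overlap.

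At least a 2-fold difference in all 4 pairings of mutant and wild-type arrays was found for 32 probe sets, 29 lower and 3 higher in the mutant. The lower ones covered 21 named genes, among them Wnt7a (-2.35), Sytl2 (-2.48) and Rassf4 (-1.40). The mutant values of Wnt7a and Sytl2 were under the dim level, Wnt7a differed by -1.19 with the pseudocount, and Sytl2 and Rassf4 were chosen after their values were seen. The same count was 40 when both arrays of replicate 2 were set against both of replicate 1, with 27 higher and 13 lower, and 1 for the remaining split. The 40 run the same way in both genotypes and so balance out between them, and their number is no chance level for the 32. With a stricter filter the genotype count was 9, all lower, against 10 for the replicate split. With a pseudocount of 16 it was 16, all lower, against 12, and after quantile normalization it was 34 (6 higher and 28 lower) against 32. After median centring 5 were higher and 28 lower, against 34 for the replicate split.

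Among the published Pax6 targets, 11 of 15 tested genes were lower and 4 higher, with a median of -0.18 (camera adjusted p = 0.00202; adjusted p = 0.598 with an estimated correlation). Adjusted over the list alone, 4 members fell in limma: Fabp7 (adjusted p = 0.000316), Dkk3 (0.00384), Dmrta1 (0.0278) and the AP-2 transcription factor Tfap2c (-0.43, 0.0315). Over all probe sets, 0 members passed. The list is not independent evidence of its direction, since its genes may have been picked on such samples. The adjusted p of the list was 0.129 without wild-type replicate 1 and 0.0647 without mutant replicate 1. The median was -0.05 without mutant replicate 1, -0.39 without mutant replicate 2 and -0.05 with no filter on dim probe sets. Without Fabp7, Dmrta1 and Dkk3, a choice made after seeing the data, the adjusted p was 0.651, and on ranks it was 0.0833. The Wnt antagonist Sfrp2 differed by -0.39 (SE 0.30), by -0.05 without mutant replicate 1, -0.73 without mutant replicate 2 and -0.24 without wild-type replicate 2.

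Genes of the ventral telencephalon were higher as a list, with 8 of 10 higher and a median of 0.22 (camera adjusted p = 0.00578; adjusted p = 0.598 with an estimated correlation). Nkx2-1, a transcription factor of the medial ganglionic eminence, differed by 0.63 (SE 0.12), Dlx1 by 0.61 (SE 0.13) and Ebf1 by 0.66 (SE 0.42). Ebf1 differed by 0.17 without mutant replicate 2, 1.16 without mutant replicate 1 and 0.36 with the pseudocount. None of these passed over the list alone (Nkx2-1 and Dlx1, limma adjusted p = 0.0774). The list's adjusted p was 0.129 without wild-type replicate 1 and 0.318 without mutant replicate 2. The median was 0.35 without wild-type replicate 2, 0.41 without mutant replicate 1 and 0.13 without mutant replicate 2.

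Neurogenesis and proneural genes were higher in 10 of 12 cases, with a median of 0.18 (camera adjusted p = 0.00578; adjusted p = 0.598 with an estimated correlation). Rgs16 differed by 0.48 (SE 0.08), the Notch pathway regulator Hes6 by 0.38 (SE 0.15) and the neuronal RNA-binding protein Elavl2 by -0.42 (SE 0.16), and 0 members passed over the list alone in limma. The adjusted p was 0.235 without wild-type replicate 1 (median 0.09), 0.0528 without mutant replicate 1 and 0.186 without mutant replicate 2 (median 0.10). The median was 0.08 with no filter on dim probe sets and 0.10 with the pseudocount. Hes6 differed by 0.24 without mutant replicate 1 and Elavl2 by -0.25 without wild-type replicate 2. Neurog2, Eomes and Neurod1 were dim in both genotypes and were not tested, as were Tbr1, Dlx5, Gad1, Emx1 and Fut9 of other lists.

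FGF signalling genes were higher in 12 of 14 cases, with a median of 0.23 (camera adjusted p = 0.0119; adjusted p = 0.598 with an estimated correlation). The patterning ligand Fgf8 differed by 0.56 (SE 0.17), the FGF-responsive factor Etv5 by 0.46 (SE 0.18) and Fgf19 by 1.01 (SE 0.73), and 0 members passed over the list alone in limma. The adjusted p was 0.129 without wild-type replicate 1 (median 0.09), 0.0703 without mutant replicate 1 and 0.338 without mutant replicate 2 (median 0.06). Without wild-type replicate 1, Fgf8 differed by 0.37, Etv5 by 0.30 and Fgf19 by 0.09, and without wild-type replicate 2 Fgf19 differed by 1.92.

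Adhesion and axon guidance genes were higher in 27 of 38 cases, with a median of 0.17 (camera adjusted p = 0.0025; adjusted p = 0.598 with an estimated correlation). Robo3, higher in the mutant, passed over the list alone (limma adjusted p = 0.0316) but not over all probe sets (limma adjusted p = 0.967). The guidance cue Ntn1 differed by 0.70 (SE 0.17) without passing. Pcdh8, a protocadherin, lay on the other side at -0.75 (SE 0.51), with -0.11 without mutant replicate 1 and -1.39 without mutant replicate 2. The difference of Robo3 was 1.04, or 0.44 with the pseudocount, and its wild-type value was under the dim level. Without mutant replicate 2 the list's median was 0.03 and its adjusted p 0.41. The median was 0.11 without wild-type replicate 2 and 0.10 with the pseudocount.

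Markers of blood and vessels were also higher in the mutant arrays. All 13 tested erythroid genes were higher, with a median of 0.43 (camera adjusted p = 2.41e-08), among them Alas2, the first enzyme of haem synthesis in red cells (0.67, SE 0.12), the red cell anion exchanger Slc4a1 (0.94, SE 0.32) and the embryonic globin Hbe1 (0.22, SE 0.07). The erythroid call held when any 1 array was left out, with a median of 0.28 without wild-type replicate 1, but the adjusted p was 0.532 with an estimated correlation. The estimated correlation of the erythroid list was -0.03, under the preset 0.01, so that higher p does not come from correlated genes. It comes with the 2 residual degrees of freedom on which that version of camera rests. Endothelial genes were higher in 17 of 20 cases, with a median of 0.16 (camera adjusted p = 0.000669, or 0.598 with an estimated correlation). The endothelial median was 0.06 without mutant replicate 2 (adjusted p = 0.0994), 0.26 without mutant replicate 1 and 0.25 without wild-type replicate 2. Plvap, a marker of endothelial fenestrae, differed by 0.65 (SE 0.18). In both lists 0 members passed over the list alone in limma. These shifts accompanied those of the ventral, neurogenesis, FGF and adhesion lists in the same arrays.

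Hypoxia and glycolysis genes were lower in 13 of 16 cases, with a median of -0.10 (camera adjusted p = 0.0025; adjusted p = 0.598 with an estimated correlation). The glucose transporter Slc2a3 differed by -0.80 (SE 0.12) and Pdk1 by -0.35 (SE 0.08), and 0 members passed over the list alone in limma. The median of this list was -0.18 without wild-type replicate 1 and -0.20 without mutant replicate 2. Lipid and fatty acid genes were lower in 13 of 20 cases, with a median of -0.07 (camera adjusted p = 0.0119; adjusted p = 0.598 with an estimated correlation). Fabp7 was the 1 member of the lipid list that fell when adjusted over the list alone (limma adjusted p = 0.000421). The lipid list's adjusted p was 0.131 without Fabp7 and 0.0509 on ranks, both choices made after seeing the data. It was 0.321 without wild-type replicate 2 (median -0.02) and 0.597 without mutant replicate 2 (median -0.04), and the median was -0.12 without wild-type replicate 1.

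The dorsal telencephalic patterning list had no shared direction, with 5 of 10 genes higher, a median of -0.01 and a mean of -0.20 (camera adjusted p = 0.968). Dmrta1 did not pass over this list (limma adjusted p = 0.0557), and Pou3f3 (0.39, SE 0.11) and Zbtb20 (0.49, SE 0.29) lay on the other side. Zbtb20 differed by 0.14 without mutant replicate 2 and 0.85 without mutant replicate 1. Genes of the cortical hem, Wnt and BMP pathways were lower in 11 of 19 cases (camera adjusted p = 0.337). Adjusted over that list alone, Msx2, a homeobox gene of the dorsal midline, passed at -0.81 (limma adjusted p = 0.0173). The Wnt agonist Rspo3 passed at -0.62 (limma adjusted p = 0.0368). Over all probe sets neither passed (Msx2, limma adjusted p = 0.967). Wnt7a (-2.35, SE 0.61, mutant value under the dim level) and the Wnt feedback target Axin2 (-0.71, SE 0.24) did not pass. With the pseudocount Msx2 differed by -0.53, Rspo3 by -0.34 and Wnt7a by -1.19, and Axin2 differed by -0.43 without mutant replicate 1.

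Among neuroepithelium and Notch genes, 14 of 25 were higher (camera adjusted p = 0.833), and Fabp7 was the 1 member that fell when adjusted over the list alone (limma adjusted p = 0.000527). Notch1 (0.41, SE 0.15) and Id4 (0.35, SE 0.32) did not pass. Id4 differed by 0.008 without mutant replicate 1, 0.69 without mutant replicate 2, 0.56 without wild-type replicate 1 and 0.14 without wild-type replicate 2. Notch1 differed by 0.24 without wild-type replicate 1. Postmitotic neuron genes were higher in 8 of 19 cases (adjusted p = 0.968), with Dcx at 0.51 (0.32 with the pseudocount), Nefm at -0.41 and Scg3 at -0.73 (-0.37 without wild-type replicate 2). Cajal-Retzius and preplate genes were higher in 4 of 6 cases (adjusted p = 0.651), with Lhx5 and Zic4 both at 0.29 and Cxcr4 at -0.15. With 1 array left out these ran from 0.10 to 0.48 for Lhx5, 0.12 to 0.46 for Zic4 and -0.26 to -0.04 for Cxcr4, lowest in size without mutant replicate 2 for Lhx5 and Zic4 and without mutant replicate 1 for Cxcr4. The 2 tested antihem genes, Fgf19 and Sfrp2, were too few for a list test.

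camera called 9 of the 23 tested lists, 6 higher and 3 lower. With an estimated correlation 0 were called, with 1 list at an unadjusted p under 0.05. That version rests on 2 residual degrees of freedom and has little power here. For the published Pax6 targets the unadjusted camera p was 0.000264 with the preset and 0.06 with the estimated correlation. The estimated correlation was -0.03 for the erythroid and -0.02 for the published Pax6 target list, under the preset 0.01. For the other lists called by camera it ran from 0.10 (adhesion) to 0.35 (ventral). In one direction fry called 0 (lowest adjusted p = 0.165), with 3 at an unadjusted p under 0.05. Tested for change in either direction, fry called 8 lists (lowest adjusted p = 0.00415). These included the published Pax6 target, adhesion, lipid and erythroid lists, which camera also called. The others were the neuroepithelium and Notch, hem, p53 response and surface ectoderm lists, which camera did not call. The ventral, neurogenesis, FGF, endothelial and hypoxia lists were not among them. Fabp7 belongs to the published Pax6 target, lipid, and neuroepithelium and Notch lists. No fry test without Fabp7 is reported here, so their calls may rest on that gene.

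**Figure D2:**
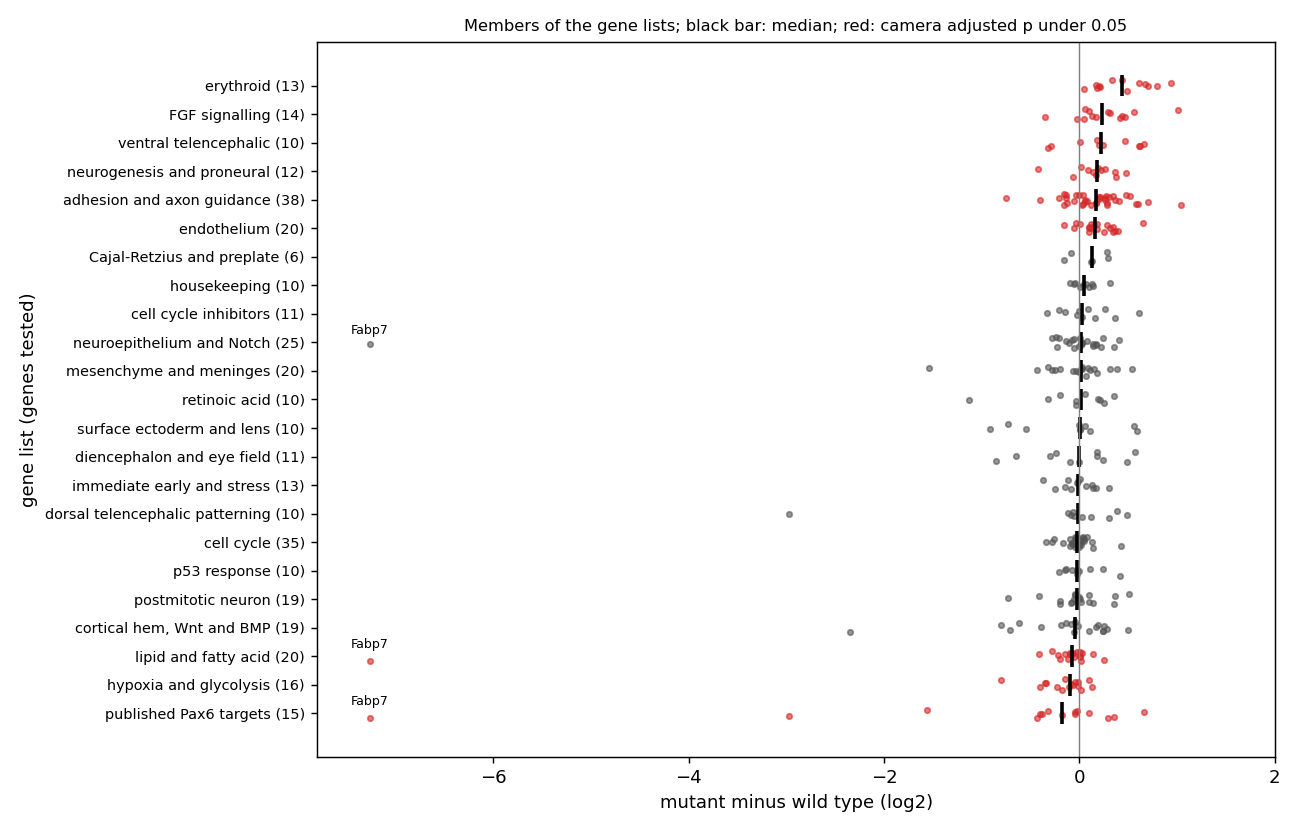
Difference between genotypes (mutant minus wild type, log2, horizontal axis) of each tested member of the 23 lists, with 1 point per gene, a black bar at the list median, and red for lists with a camera adjusted p under 0.05. Medians run from -0.18 for published Pax6 targets to 0.43 for erythroid genes, and Fabp7 at -7.26 belongs to 3 of the lists.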

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

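The added tests without zero-variance probe sets, on ranks and with members left out were chosen after seeing the data. Against 0 probe sets in the reported limma fit (680 at an unadjusted p under 0.05), the stricter filter called 1, quantile normalization 2, median centring 2 and leaving out 249 zero-variance probe sets 2, all lower. In that order, their eBayes prior degrees of freedom, the weight of the variance shared by probe sets, were 2.55, 2.38, 3.32 and 1.93. The reported fit had 1.25 and the fit with no filter 0.375. Whether this weight alone made the calls was not tested. Fabp7 was in each of these calls, and its difference ran from -7.43 to -6.58 over all alternatives, with adjusted p from 0.00317 to 1. No filter, the trend, robust and unmoderated tests, the pseudocount, the looser threshold and each left-out array called 0, with lowest adjusted p from 0.0906 to 1. The count of 32 probe sets with 2-fold differences was 9 with the stricter filter, which tested fewer probe sets, and 16 with the pseudocount, which shrinks low values. Of 9 lists, 0 were called with an estimated correlation and 0 by fry; leaving out 1 array gave 3 (without mutant replicate 2) to 8, with fewer arrays, and 5 without wild-type replicate 1. The robust and unmoderated tests have no counterpart in camera. The Pax6 difference stayed between -0.17 and -0.02. Signal limits low genes: 12417 dim probe sets were not tested.

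With the replicate number as a replicate block, 0 probe sets (lowest adjusted p 0.736, 1194 at an unadjusted p under 0.05, above the 931 expected by chance) and 9 lists were called. Deviations of same-numbered arrays correlated at 0.435 over probe sets. Each array was closest to the same-numbered array of the other genotype, with correlations of 0.9931 for replicate 1 and 0.9932 for replicate 2. Within a genotype the correlation was 0.9923 for wild type and 0.9894 for the mutant. Same-numbered arrays thus shared a difference, which the reported fit counts as spread within a genotype. That fit had 680 probe sets at an unadjusted limma p under 0.05, against 1194 with the block. Still, 2 pairs do not show that the numbers pair the samples, and the labels do not say so.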

Other observations

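The tests of a level-dependent shift, of sex-linked genes and of values near the floor were chosen after the results were seen; those of the second erythroid list and of linkage were written before.

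Several gene groups outside forebrain patterning did not pass as lists in camera. Among 35 cell cycle genes 23 were lower, with a median of -0.02 (camera adjusted p = 0.303), with Ccnd1 at 0.43 (0.22 without wild-type replicate 1) and Top2a at -0.34. Cell cycle inhibitors (adjusted p = 0.88) included the kinase inhibitor Cdkn1c at 0.61. In the retinoic acid list (adjusted p = 0.88) the receptor Rarb differed by -1.13 (SE 0.26), with a list median of 0.01 and mean of -0.06. Immediate early and stress genes (adjusted p = 0.88) and p53 response genes (adjusted p = 0.968, median -0.03, mean 0.02) included Jun at -0.37 and Plk2 at 0.42. For change in either direction, fry called the p53 response list (adjusted p = 0.00505). Housekeeping genes had a median of 0.05 (adjusted p = 0.651).

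Markers of neighbouring tissue did not pass as lists in camera either. Diencephalon and eye field genes had 5 higher and 5 lower among 11 (camera adjusted p = 0.965, median 0, mean -0.04), with Rax at 0.57 (0.31 without wild-type replicate 1) and Sim2 at -0.86. Surface ectoderm and lens genes had a camera adjusted p of 0.965, a median of 0.01 and a mean of -0.08. Krt18 differed by -0.73 and passed over that list alone (limma adjusted p = 0.04), but not over all probe sets. For change in either direction, fry called this list (adjusted p = 0.00699). Mesenchyme and meninges genes had a median of 0.02, a mean of -0.06 and a camera statistic in the higher direction (adjusted p = 0.987), with the matrix protein Postn at -1.54 (-1.01 without wild-type replicate 2, mutant value under the dim level). The median, mean and camera direction also differed in sign for the dorsal list (camera higher) and for neuroepithelium and Notch (median 0.02, mean -0.27). Neural crest (4 genes, median 0.11), macrophage and immune (2 genes, median -0.05), antihem (2 genes, median 0.31) and sex-linked genes (3 genes, median 0.13) had too few members for a list test.

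For the higher erythroid markers in the mutant arrays, a shift of all genes at that level is argued against, since 0 of 10000 random lists matched on mean level reached the erythroid median of 0.43. A second list of 26 erythroid genes had 18 tested genes, 0 of them in a fixed list, with a median of 0.159. Of these, 10 lay apart and higher. For a single gene with exchangeable arrays the chance of this is 16.7%. Genes that vary together on the same arrays are not independent, so the count of 10 does not exclude chance. A candidate explanation is more red blood cells in the mutant pools, although 17 of the 18 genes were above the dim level in wild type and the tissue may express many of them. The globins Hbe1 (wild-type value 15.19), Hbg1 (14.97) and Hbz (14.80) differed by 0.22, 0.20 and 0.18. These values lie near the array maxima of 16.05 to 16.13, where differences may be compressed. The globin Hbb differed by 0.05 (-0.27 without mutant replicate 1, 0.37 without mutant replicate 2). Hbe2, another globin, differed by 0.70 (0.20 without mutant replicate 1, 1.21 without mutant replicate 2). Prdx2 differed by 0.13 (0.06 without mutant replicate 1, 0.20 without mutant replicate 2). Tfrc differed by -0.03 (-0.09 without wild-type replicate 1, 0.04 without wild-type replicate 2). Dissection, red cell stage and the genotype itself stay open, untested.

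Sex-linked transcripts had different values in the pools, none past the threshold (limma adjusted p = 1). Eif2s3y, on the Y chromosome, differed by 1.29 (95% interval -0.29 to 2.88; 0.65 without wild-type replicate 2, 1.94 without wild-type replicate 1), and 4 of 4 Xist probe sets were lower, by -0.46 to -0.79. Without wild-type replicate 2 the Xist probe sets at -0.46 differed by -0.08 and -0.26, and without wild-type replicate 1 the first of these differed by -0.84. The Xist probe sets at -0.79 (95% interval -1.13 to -0.45) and -0.76 (-1.03 to -0.49) were steadier. With any 1 array left out they ran from -0.69 to -0.89 and from -0.69 to -0.83. A larger share of male embryos in the mutant pools may account for this, but Uty, the other tested Y-linked gene, differed by 0.132 (95% interval -1.05 to 1.32), and its sign turned without wild-type replicate 2 (-0.10) and without mutant replicate 1 (-0.30), against 0.36 without wild-type replicate 1 and 0.56 without mutant replicate 2. The explanations cannot be told apart, since the interval of Uty holds both 0 and the estimate of Eif2s3y.

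Of the probe sets at least 2-fold different, 29 were lower in the mutant. Values near the floor are argued against as the whole cause, since 22 of 29 had both group means above the dim level, but only 14 of these also stayed 2-fold with the pseudocount of 16, and the floor stays open for the others. Alleles linked to Pax6 are argued against as the whole cause, since 20 of 21 placed lower genes lie on other chromosomes, or 21 of 22 with Kcnip4, which was higher (4.55% of the 22 on the chromosome of Pax6, against 7.72% of 9812 other genes; Fisher's exact test p = 1). Linkage stays open for Lrrc4c, which lies 40 protein-coding genes from Pax6. An effect of the genotype stays open, untested.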
